A study of Mus musculus with 34 samples.

How the data were processed

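Chromatin of 2 mouse embryonic fibroblast lines, MEFB and MEFF, was immunoprecipitated for 9 histone marks and hybridised against input of the same line on 2-colour tiling arrays of chromosome 17, per the labels. The DNA was amplified with T7 polymerase and hybridised by NimbleGen, per the labels. ChIP DNA carried Cy5 on 16 arrays and Cy3 on 18, per the labels. Each array came as 2 deposited files of spot intensity as scanned, 1 for 532 nm (Cy3) and 1 for 635 nm (Cy5), extracted with NimbleScan 2.2.1e (2 arrays), 2.2.26 (11), 2.2.34 (4), 2.3.2d (9) and 2.3.4 (8), per the file headers. The deposited value table holds the log2 ratio of ChIP over input shifted by 1 constant per array and rounded, as found by comparing it with the intensity files. How that constant was chosen is not given in the sources used here. Per the file headers the images were extracted on 10 days, and the image of MEFF H3K9Ac replicate 1 was a rescan.

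Arrays were grouped by line and mark into 18 groups, as the labels give them. The arrays came in 3 designs of 390143 probes (27 arrays), 389237 probes (5) and 390604 probes (2). The last design carries no positions in its files, so its 2 MEFB H3K4me2 arrays entered no window. The 378094 positions shared by the other designs, 97.5% of the largest, have a median spacing of 145 bp. The genome build of these positions is not given in the sources used here. Of the positions, 1686 fall in unsequenced stretches of NCBIM37 chromosome 17, so they were not taken to be of that build. No annotation was joined to them, which left out the planned gene and promoter comparisons and the gene lists. No more than 0.230% of the probes of any array reached an intensity of 65000.

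From the intensities, log2 (ChIP/input) was computed per probe with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, and matplotlib 3.10.9 for plots) and centred on each array's median, without background subtraction. Probes were averaged in windows of 10 kb with at least 10 probes (8241 windows, median 47 probes). Windows of 1 kb (at least 3 probes), 2 kb (at least 5), 50 kb, 100 kb and 1 Mb served for scale. On 2 arrays, MEFF H3K27me3 replicate 2 and MEFB H3K4me3 replicate 1, the deposited log2 values run opposite to the labelled dyes. The deposited direction was used, since with it both arrays correlate positively with the other arrays of their mark, and the labelled direction was an alternative.

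Lines were compared within each of 8 marks in 1 joint fit of all placed arrays with limma 3.58.1 in R 4.3.3, with group means and a dye term (13 residual degrees of freedom, prior 8.15). The p-values were adjusted by the Benjamini-Hochberg method within a mark, and windows were called at an adjusted p of 0.05. In this fit all marks shared 1 residual spread per window, so a mark's p-values do not rest on the spread of its own arrays alone. Groups of 1 array took their spread from the others. MEFB H3K9me3 replicates that share a number in the labels (r = 0.759, against a median of 0.657 for the other H3K9me3 pairs) were averaged and counted once. The windows named are the 5 largest called differences per mark and direction and the 5 highest windows per mark by the lower of the 2 line means, and others are said to have been chosen after their values were seen. Enrichment was a mean of at least 0.5 in both lines. Similarity of arrays was tested by permuting marks within lines (100000 resamples, 20000 for alternatives), and correlation between marks by 1000 shifts of one profile along the chromosome, leaving out shifts under 2% of its length. Called windows no more than 100 kb apart were joined into clusters.

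The groups, tests, rule for named windows and a first set of other settings were fixed before the data were examined. These settings were normexp background correction (offset 50), loess within arrays (span 0.3), quantile normalization, no dye term, array design as a term, each mark fitted alone, windows of 2 and 50 kb, all probes, leaving out the dimmest 10% of probes, the deposited values, a threshold of 1, Spearman's rho, and leaving out each array in turn. Others were chosen after seeing the data: the labelled dye direction, leaving out the 2 conflicting arrays, equal spread per array, extraction day as a term, same-day pairs, and the input brightness regressed out with a polynomial of degree 3. The Thp segment was to be found as a run of low input between 5 and 20 Mb (running median of 5 windows of 100 kb, 5th percentile). The input of 27 arrays showed 1 run, 0.3 Mb long at 18.8 to 19.1 Mb, too short for that segment. The comparison inside and outside the segment was therefore not made. A segment of at least 4.6 Mb would take up nearly all windows that the 5th percentile of 902 windows lets through. The search could thus hardly have found it and does not show that the input lacks such a segment.

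The line test was checked on simulated data for 8241 windows with 200 changed per mark. All marks were given the same spread in a window and 1 common dye effect, as the fit assumes. It called 0 to 46.5% of changes of 0.5, 87.5% to 100% of changes of 1.0 and 99% to 100% of changes of 1.5 on the log2 scale, with 0 wrong signs. The shift test gave p under 0.05 in 3.0% of 200 unrelated and 100% of related simulated pairs.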

Results

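Histone modifications were mapped along mouse chromosome 17 by native chromatin immunoprecipitation (ChIP without cross-linking) on tiling arrays that carry DNA probes at regular steps. The material came from 2 spontaneously immortalised embryonic fibroblast lines of the FVBN strain, MEFB and MEFF, both from embryos at 12.5 days post coitum. MEFB has the genotype +/Thp and MEFF the genotype Thp/+, so each lacks the same segment on a different parental chromosome. The labels place the start of that segment at 8.6 Mb in mm9 and give it a length of at least 4.6 Mb. They put the 400 kb Igf2r imprinted cluster inside it. On each array ChIP DNA competed with input DNA of the same line. The marks were H3 acetylation (H3Ac), H4 acetylation (H4Ac), H3K9Ac, H3K4me2, H3K4me3, H4K20me1, H3K27me3, H3K9me3 and H4K20me3. There were 34 arrays, 17 per line, and 32 had probe positions. The other 2, both MEFB H3K4me2, had none, so H3K4me2 was placed in MEFF alone. Median probe intensity per array was 501 to 2209 in the ChIP channel and 1290 to 4387 in the input channel, and the number of arrays, 1 or 2 replicates per line and mark, limits the precision.

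Levels below are mean log2 ratios of ChIP over input relative to the median of chromosome 17, with the SD over replicates, in 10 kb windows given by their start. Positions are those of the array files, whose build was not given in the sources used here, so the windows were assigned to no gene and the mm9 segment was not laid over them. For 2 arrays the deposited ratio ran opposite to the labelled dyes. MEFF H3K27me3 replicate 2, read by its labels, correlated at -0.80 with the MEFB array and at -0.88 with MEFF replicate 1. MEFB H3K4me3 replicate 1 correlated at -0.90 and -0.49 with the MEFF arrays and at -0.78 with the other MEFB array. In the deposited direction the same correlations were positive, which argues against the labelled direction for both arrays. No source used here says why label and value conflict. The deposited direction was used and the labelled one kept as an alternative. Values by the labels are given for enriched shares, leading windows, called windows and correlations between marks, but not for the overlaps, runs and clusters of H3K27me3 and H3K4me3. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. In the line tests that spread was pooled over all marks.

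The first question was how much of the chromosome each mark covered. H3Ac, H3K27me3 and H3K9Ac stood at 0.5 or more in both lines in 6.75%, 4.94% and 4.53% of 8241 windows, H4Ac in 3.93%, H4K20me1 in 1.59% and H3K4me3 in 1.24%. H3K4me2 reached this level in 6.38% of windows in MEFF, the 1 line measured. H4K20me3 did so in 0.206% and H3K9me3 in 0.0728%, which is 17 and 6 windows. The SD between single arrays was 4.49 points for H3Ac, 1.80 for H3K27me3 and 5.22 for H3K9Ac, so the order of these marks lay within the spread. These levels are relative to the chromosome's median and not to untargeted probes. On the 5 arrays that carry them, control probes named chr2L had a median log2 ratio of 0.38 and 0.41 (MEFF H3K4me2), 0.55 (MEFF H3K4me3 replicate 1), 0.53 (MEFB H3K4me3 replicate 1) and 0.67 (MEFB H3K9me3 replicate 3), above 0.5 on 3 of the 5 in the deposited direction. With loess within arrays the shares fell to 1.33% for H3Ac, 1.09% for H3K27me3 and 0.692% for H4Ac, and H4K20me1 stood at 0.498%, while H3K9Ac stood at 5.33%, the highest of the 8 marks measured in both lines, and H3K4me2 at 6.33% in MEFF. With normexp background correction the shares were 9.51% for H3K27me3, 8.49% for H4Ac, 10.01% for H3K9Ac, 15.1% for H3K4me2, 3.86% for H3K4me3, 6.99% for H4K20me3 and 2.97% for H3K9me3. With the dyes as labelled, H3K27me3 and H3K4me3 reached 0.5 in both lines in 0 windows. Leaving out MEFB H4K20me1 replicate 1 or 2 gave 0.655% or 3.01%, leaving out MEFB H3K4me3 replicate 1 or 2 gave 0.425% or 2.09%, and leaving out MEFB H3K9Ac replicate 1 gave 2.45%. H3K9me3 fell to 0.0121% without MEFB replicate 2 or replicate 3 and stood at 0.243% without MEFB replicate 1 and 0.133% without MEFF replicate 1.

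Enriched windows of the active marks overlapped, and the windows below are ranked by the lower of the 2 line means. H3K4me2 and H3K4me3 mark active or poised promoters. The window at 44.43 Mb led H3K9Ac, with 2.00 ± 0.96 in MEFB and 1.64 ± 0.26 in MEFF (n = 2 each), and H3K4me2, with 2.25 ± 0.07 in MEFF (n = 2). The window at 31.85 Mb ranked first for H3K4me3, with 1.18 ± 0.66 in MEFB and 1.52 ± 0.03 in MEFF, and had H3K4me2 at 1.97 ± 0.03 in MEFF, while 22.14 Mb had more H3K4me3 in MEFF, 1.76 ± 0.05, and less in MEFB, 1.08 ± 0.51. Of the 102 windows enriched for H3K4me3, 100 were also enriched for H3K4me2, 97 for H3K9Ac and 94 for H3Ac, where independent lists would share 6.51, 4.62 and 6.88. H3Ac and H3K9Ac were both high at 32.31 Mb, where H3Ac was 1.68 ± 0.41 in MEFB and 1.54 ± 0.28 in MEFF, and at 83.36 Mb. H4Ac ranked 34.06 Mb first, with 1.12 ± 0.04 in MEFB and 1.43 ± 0.37 in MEFF. H4K20me1 ranked 27.63 Mb first, with 1.45 ± 0.40 and 1.78 ± 0.27, and 53 of its 131 enriched windows also carried H3Ac against 8.84 for independent lists.

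H3K27me3, the mark of Polycomb silencing, had its enriched 10 kb windows elsewhere. By the same ranking it was highest at 33.91 Mb, with 2.05 in MEFB (n = 1) and 2.01 ± 0.07 in MEFF (n = 2), and at 44.64 Mb, with 2.18 and 1.89 ± 0.22. Of its 407 enriched windows, 0 were enriched for H4Ac, 1 for H3K9Ac and 5 for H3Ac, where independent lists would share 16.0, 18.4 and 27.5. No test was run on these overlaps, because neighbouring windows are not independent. The separation holds for enriched windows, whereas the whole profiles of H3K27me3 and H3Ac correlated above 0. In MEFB they did so at 0.22 over 10 kb windows, 0.42 over 100 kb and 0.82 over 1 Mb. In MEFF the values were 0.13 (-0.21 by the labels), 0.26 and 0.50. H3K27me3 with H4Ac stood at -0.11 in both lines over 10 kb. Over 1 Mb it stood at 0.65 in MEFB and 0.42 in MEFF. H4K20me3 and H3K9me3, marks of constitutive heterochromatin, stayed low. In their first-ranked windows H4K20me3 reached 0.66 in MEFB and 0.67 in MEFF at 37.44 Mb (n = 1 each), and H3K9me3 reached 0.65 ± 0.30 and 0.69 ± 0.06 at 80.37 Mb (n = 2 each), whereas in MEFF alone H4K20me3 had 0.77 at 92.57 Mb and H3K9me3 0.83 ± 0.15 at 16.90 Mb. Enriched windows of H4K20me3 had a median input brightness at percentile 0.498 of all windows and those of H3K9me3 at 19.5, whereas the other marks' enriched windows stood between 60.9 and 77.3. With the dyes as labelled the 2 affected marks had other leading windows: H3K27me3 peaked at 45.18 Mb with 1.34 in MEFB and 0.34 in MEFF, and H3K4me3 at 88.57 Mb with 0.22 in both lines.

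The marks also differed in how far their signal extended. Across 1 kb windows H3K27me3 correlated with itself at 0.569 ± 0.0446 over 1 kb and 0.379 ± 0.0441 over 10 kb (SD, 3 arrays), and at 0.146 ± 0.0408 over 100 kb. H3Ac held 0.379 ± 0.0782 over 10 kb, 0.320 ± 0.0698 over 100 kb and 0.168 ± 0.0393 over 1000 kb (4 arrays), the highest of the 9 marks at the 100 and 1000 kb distances. H3K4me2 was focal, with 0.495 over 1 kb and 0.0757 ± 0.0029 over 10 kb (2 arrays), and H3K4me3 went from 0.294 ± 0.0635 to 0.0698 ± 0.0441 (4 arrays). H3K9me3 was at 0.180 ± 0.0551 and H4K20me3 at 0.215 ± 0.0343 over 1 kb. No test was made between marks. The median run of adjacent enriched windows was 10 kb for all 9 marks, and the longest was 120 kb, for H3Ac and for H3K9Ac.

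**Figure D1:**
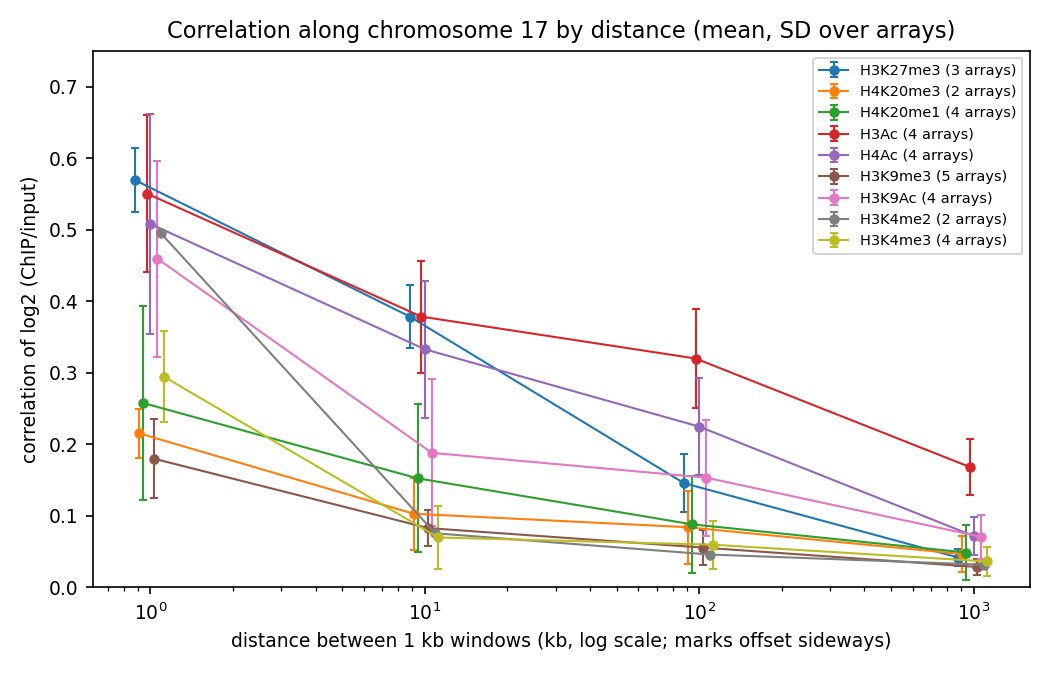
Correlation of log2 (ChIP/input) between 1 kb windows of chromosome 17 (vertical axis) against their distance in kb on a log scale, as mean and SD over the arrays of each mark. H3Ac stays at 0.320 over 100 kb while H3K4me2 is at 0.0757 over 10 kb.

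The next comparison asked whether the lines shared their profiles. Arrays of the same mark in different lines had a mean Pearson correlation of 0.723 over 10 kb windows (27 pairs), and arrays of different marks 0.213 (183 pairs). The gap of 0.510 had p = 1e-05 in a one-sided permutation test with 100000 resamples, the smallest p that it can give. Among arrays whose images were extracted on the same day the gap was 0.576 (p = 0.00085, permutation test), and with the dyes as labelled it was 0.377 (p = 5e-05, the smallest p of 20000 resamples). H3Ac profiles correlated at 0.900 within a line and 0.857 between lines, and H4Ac at 0.914 and 0.755. H4K20me1 profiles correlated at 0.469 within a line and 0.621 between lines. For H3Ac, H4Ac and H4K20me1 the arrays of a line carried opposite dyes, whereas some pairs between lines shared a dye. Values within and between lines therefore cannot be compared apart from dye. Among all pairs of opposite dye the same-mark mean was 0.657 (13 pairs) and the gap 0.419 (p = 5e-05, permutation test).

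H3K27me3 had the most called windows between MEFB and MEFF, 125 against 41 for H4Ac, but H4Ac had more at an unadjusted p under 0.05 (1004 against 898). H4Ac also had more calls after loess (271 against 152), after quantile normalization (487 against 327) and with each mark fitted alone (403 against 192). H3K27me3 was higher in MEFF in 104 windows and higher in MEFB in 21, with a median difference of 0.74 among the called windows. At 78.45 Mb it stood at 0.12 in MEFB (n = 1) and 1.61 ± 0.11 in MEFF (n = 2), a difference of -1.47 (MEFB minus MEFF, SE 0.16, limma adjusted p = 8.81e-05), and at 13.70 Mb at -0.16 against 1.13 ± 0.45 (-1.28, limma adjusted p = 0.00145). The windows at 13.30, 78.85 and 84.02 Mb followed, at -1.11, -1.12 and -1.10. In 62 of the 104 windows, or 59.6%, MEFB lay under 0.1, that is, near or below the chromosome's median. Windows higher in MEFB included 48.10 Mb, with 0.43 against -0.66 ± 0.19 (+1.11, limma adjusted p = 0.0402), 33.16 Mb at +1.06 and 47.77 Mb at +1.05.

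The H3K27me3 windows higher in MEFF formed blocks. Joining calls no more than 100 kb apart gave 36 clusters, and 11 of them with at least 3 calls held 72 of the 104. The largest cluster ran from 13.11 to 13.52 Mb with 17 calls, at 0.02 in MEFB and 0.81 in MEFF on average. Others ran from 11.11 to 11.42 Mb (13 calls), from 11.83 to 12.07 Mb (8 calls), from 9.82 to 10.01 Mb (6 calls) and from 13.63 to 13.76 Mb (6 calls). A stretch of 4.6 Mb starting at 9.82 Mb, whose last call ended at 14.16 Mb, held 56 of the 104, or 53.8%, in 5.08% of all windows. Its length was taken from the labels and its place from the calls, after they were seen. The mm9 position of the segment in the labels was not compared with it, since the build of the array positions is not given. Placing the calls at random in 100 kb blocks 10000 times put a median of 16 and at most 30 into the fullest such stretch (permutation p = 0.0001, the smallest it can give). The largest cluster, of 410 kb, is longer than the blocks. This placement therefore broke clusters up and cannot tell how often whole clusters would fall together.

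All 3 H3K27me3 arrays were extracted on 1 day. By the labels ChIP DNA carried Cy5 on the MEFB array and Cy3 on both MEFF arrays, which ties dye to line for this mark. In the deposited direction MEFF replicate 2 carried Cy5. Scaling every array to equal spread turned the split to 123 higher in MEFB and 84 higher in MEFF, with 44 of the 84 in the same stretch, and loess gave 10 and 142. With the dyes as labelled limma called 0 windows, 835 at an unadjusted p under 0.05, and the differences at 78.45, 13.30 and 84.02 Mb turned to 0.093, 0.0449 and 0.071. Without MEFF replicate 1 there were 14 calls, without MEFF replicate 2, the array of unsettled direction, 96, and MEFB has 1 array whose spread was taken from the other groups.

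H4Ac was higher in MEFF in 34 windows and in MEFB in 7. At 84.16 Mb it was 0.36 ± 0.11 in MEFB and 1.22 ± 0.20 in MEFF (n = 2 each, -0.86, SE 0.15, limma adjusted p = 0.0163), and at 49.76 Mb -0.24 ± 0.00 and 0.57 ± 0.04 (-0.82, limma adjusted p = 0.00826). The window at 49.76 Mb lay in the one H4Ac cluster of at least 3 calls, which held 5 calls from 49.76 to 49.97 Mb. H4Ac was higher in MEFB at 66.40 Mb, with 0.56 ± 0.00 against -0.23 ± 0.18 (+0.80, limma adjusted p = 0.0176), and in 4 windows between 47.95 and 48.30 Mb, at +0.71 to +0.78. Arrays of the same extraction day, 1 per line, differed in these windows by a median of 0.62 against the fitted 0.68, but the windows had been selected with these arrays, so their direction is no separate check. With the day as a term limma called 10 windows, all higher in MEFF, and 7 of them were among the 41. The calls rested on every array: leaving out MEFB replicate 1 left 1 call, MEFB replicate 2 left 0 (1171 at unadjusted p under 0.05, limma), MEFF replicate 1 left 0 (498) and MEFF replicate 2 left 6. The split was 168 and 319 after quantile normalization and 28 and 73 at equal spread. With the dyes as labelled limma called 0 windows (455 at unadjusted p under 0.05). That setting turns no H4Ac array, and the median differences stayed at -0.68 in the 34 windows and +0.71 in the 7. Only the spread that the joint fit shares between marks had changed.

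H3K9Ac differed in 8 windows. In MEFB it was high at 78.25 Mb, with 1.76 ± 0.88 against 0.12 ± 0.03 in MEFF (n = 2 each, +1.64, SE 0.21, limma adjusted p = 0.000557), at 84.25 Mb (+1.39), 66.37 Mb (+1.04), 62.01 Mb (+0.93) and 71.51 Mb (+0.62). The SE at 78.25 Mb came from the spread pooled over all marks and is small beside the SD of its own MEFB arrays. In MEFF it was higher at 30.03 Mb, with -0.21 ± 0.03 in MEFB and 0.63 ± 0.17 in MEFF (-0.84, limma adjusted p = 0.00017), at 12.15 Mb (-0.79, limma adjusted p = 0.0333) and at 49.76 Mb (-0.78). The 3 windows higher in MEFF also had lower H4Ac in MEFB, by a median of -0.76, and 2 of them were called for H4Ac. H3K4me3 had 1 called window, again at 30.03 Mb, with -0.31 ± 0.01 in MEFB and 0.34 ± 0.04 in MEFF (-0.64, limma adjusted p = 0.0176).

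Within one extraction day the called H3K9Ac windows differed by a median of 0.89 against the fitted 0.88 (2 MEFB arrays and 1 MEFF array), and the H3K4me3 window by 0.61 against 0.64, again in windows selected with these arrays. With the day as a term limma called 0 windows for both, with 808 and 45 at an unadjusted p under 0.05. Leaving out MEFB H3K9Ac replicate 2 raised the count to 513, while 2 were left without MEFB replicate 1, 3 without MEFF replicate 1 and 3 without MEFF replicate 2. The H3K9Ac split was 13 in MEFB and 20 in MEFF after loess, 20 and 5 after quantile normalization and 11 and 16 at equal spread. With each mark fitted alone limma called 0 windows for both marks (lowest adjusted p = 0.271 and 0.978, with 302 and 208 windows at an unadjusted p under 0.05). The H3K4me3 call was lost without MEFB replicate 1, MEFB replicate 2 or MEFF replicate 1, each with 0 calls in limma (326, 344 and 2049 windows at an unadjusted p under 0.05), and without MEFF replicate 2 the 1 call was another window. With the dyes as labelled limma called 0 windows for H3K9Ac (337 at unadjusted p under 0.05) and 0 for H3K4me3 (820). That setting turns no H3K9Ac array. The H3K9Ac medians stayed at +1.04 in the 5 windows higher in MEFB and -0.79 in the 3 higher in MEFF, so only the shared spread had changed. The H3K4me3 difference at 30.03 Mb went from -0.64 to -0.34.

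**Figure D2:**
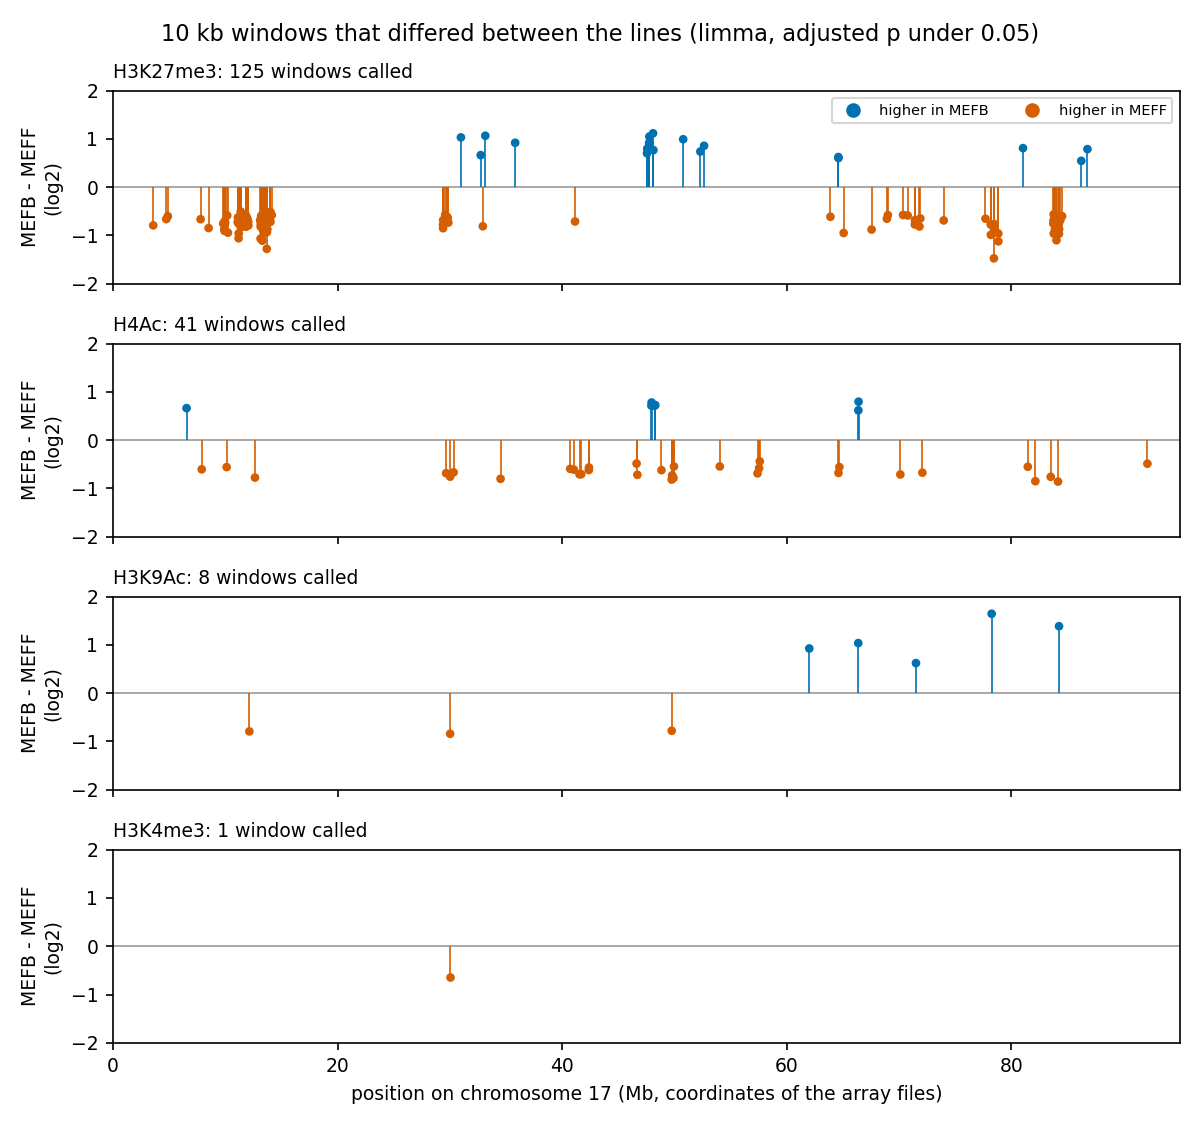
Difference in log2 (ChIP/input), MEFB minus MEFF, of each 10 kb window that passed limma's adjusted p of 0.05 against its position on chromosome 17 in Mb, with 1 panel per mark, blue for higher in MEFB and orange for higher in MEFF. The 125 H3K27me3 windows include 104 higher in MEFF, crowded between 9.82 and 14.16 Mb.

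The other 4 marks compared gave 0 called windows in limma at 10 kb. H3Ac came nearest, with a lowest adjusted p of 0.0582 and 462 windows at an unadjusted p under 0.05, and in windows of 50 kb it was higher in MEFB in 13 and in MEFF in 0 (lowest limma adjusted p = 0.0113). H4K20me1 had 161 windows at an unadjusted p under 0.05, H3K9me3 619 and H4K20me3, with 1 array per line, 36. By chance alone a fraction of 0.05 of the 8241 windows would reach such an unadjusted p. A count of them by itself therefore does not show a difference. H3Ac had 41 calls higher in MEFB and 1 in MEFF at equal spread and 76 and 8 after quantile normalization. H4K20me1 fitted alone had 261 calls. In simulated data with 200 changed windows, a difference of 1.0 was called in 87.5% of them for H4K20me3 and in 98.5% to 100% for H3K9me3 and H4K20me1, and a difference of 0.5 in 0 to 46.5% over the 8 marks. The simulated marks met the fit's assumptions of equal spread and 1 common dye effect. These rates therefore do not show how often differences in the data were missed.

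Windows of 2 kb resolved sharper differences, and those named here were chosen after their values were seen. H3K4me3 was higher in MEFF in 4 such windows, which started at 12150001, 24352001, 26146001 and 76928001. At 12.150 Mb (chromosome 17, 12150001 to 12152000) it was -0.04 ± 0.28 in MEFB and 1.99 ± 0.28 in MEFF (n = 2 each, -1.99, limma adjusted p = 0.00208). H3K9Ac there was -0.06 ± 0.19 and 1.78 ± 0.35 (-1.84, limma adjusted p = 0.00145), H3Ac -0.12 ± 0.05 and 1.05 ± 0.36 (limma adjusted p = 0.199), and H3K4me2 in MEFF 1.28 ± 0.21. The next window, 12152001 to 12154000, had H3K9me3 at 1.47 ± 0.23 in MEFB and -0.32 ± 0.20 in MEFF (+1.77, limma adjusted p = 0.0153). A window 26 kb away, 12176001 to 12178000, had the opposite order, with H3Ac at 1.20 ± 0.14 in MEFB and -0.30 ± 0.08 in MEFF (limma adjusted p = 0.199), H3K9Ac at 1.42 ± 1.13 and -0.12 ± 0.05 (limma adjusted p = 0.0622) and H3K4me3 at 1.17 ± 0.56 and 0.37 ± 0.36 (limma adjusted p = 0.916), none past the threshold. H3K9me3 had 2 more calls, both higher in MEFF, from 12260001 (limma adjusted p = 0.0225) and from 23802001 (-1.34), and H4K20me1 had 1, from 86582001 (-1.29, limma adjusted p = 0.0122). With the dyes as labelled the H3K4me3 difference at 12.150 Mb was -2.19 (limma adjusted p = 0.000795), the one at 12.176 Mb turned to -0.76, the H3K9me3 window lost its call (+1.75, limma adjusted p = 0.0717), and H3K4me3 had 416 calls at 2 kb.

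**Figure D3:**
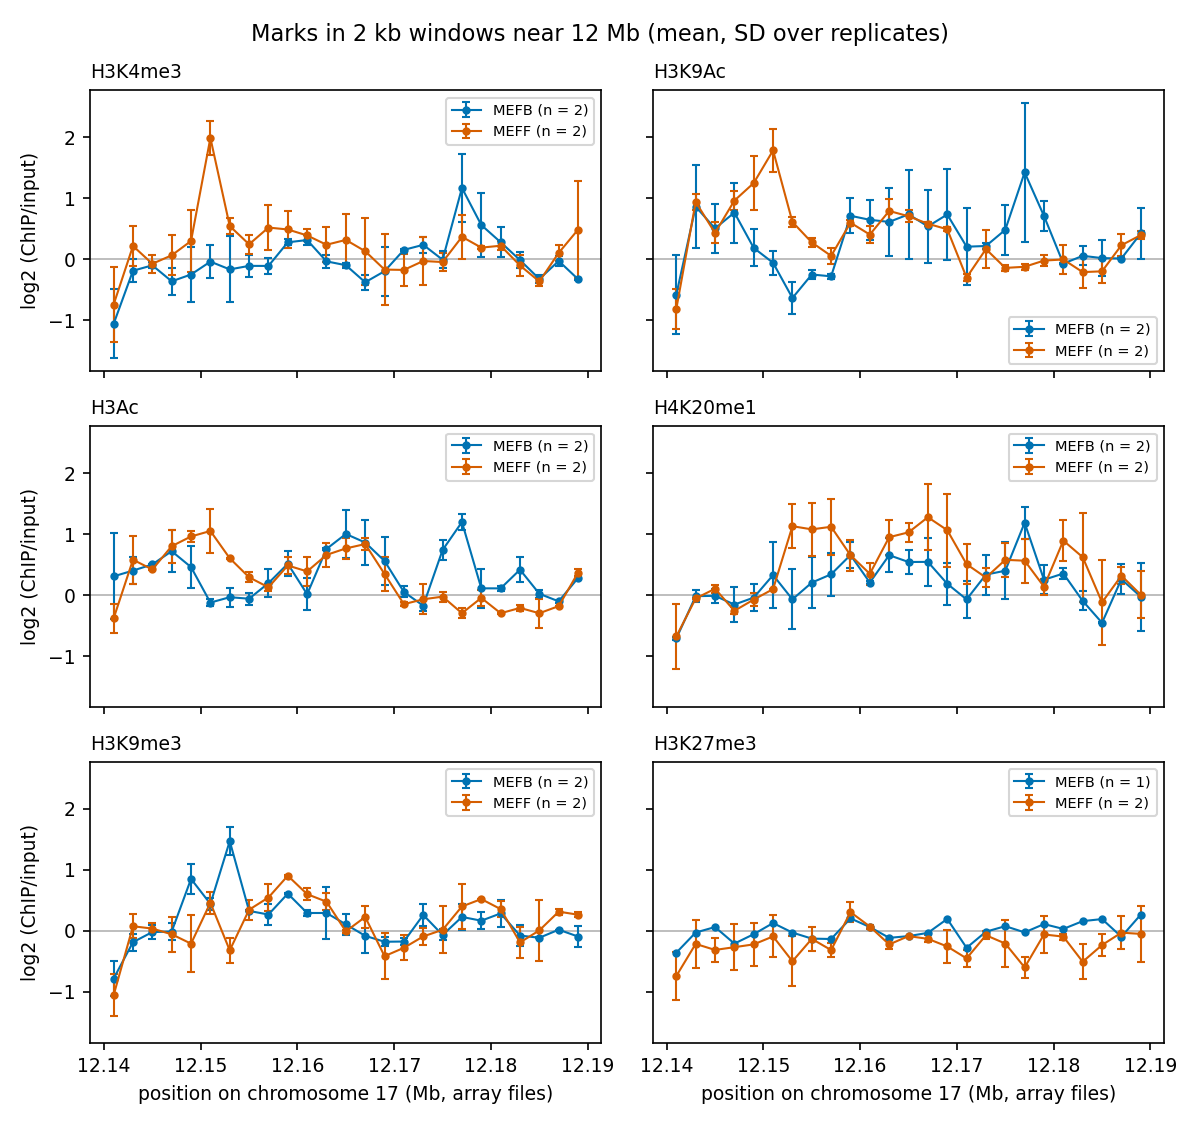
Mean log2 (ChIP/input) with SD over replicates in 2 kb windows of chromosome 17 between 12.14 and 12.19 Mb, for 6 marks in MEFB (blue) and MEFF (orange). H3K4me3 peaks at 1.99 in MEFF at 12.150 Mb, and H3Ac at 1.20 in MEFB at 12.176 Mb.

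The last comparison asked how the marks tracked one another along the chromosome. The 3 acetylation profiles rose and fell together. In MEFB H3Ac correlated with H4Ac at 0.72 and with H3K9Ac at 0.70, and H4Ac with H3K9Ac at 0.76. In MEFF H3K4me2 correlated with H3K4me3 at 0.83 and with H3K9Ac at 0.76. H4K20me3 and H3K9me3 correlated at 0.76 in MEFB and 0.86 in MEFF. H3Ac opposed both of them in MEFB, at -0.53 with H4K20me3 and -0.48 with H3K9me3. In MEFF it stood at -0.14 with H4K20me3 and at -0.0023 with H3K9me3 (p = 0.95, permutation by shifts). Of 28 mark pairs in MEFB, 15 correlated above 0 and 9 below 0 past an adjusted p of 0.05, and of 36 pairs in MEFF, 28 and 4. Each other pair named so far in this paragraph had a permutation p of 0.001 (adjusted 0.0012). That is the smallest p that 1000 shifts of one profile along the other can give. These correlations run across windows, which are not independent replicates. Spearman's rho was 0.75 and 0.85 for H4K20me3 with H3K9me3 and -0.55 for H4K20me3 with H3Ac in MEFB.

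After loess within arrays 1 MEFB pair and 2 MEFF pairs correlated below 0 past the threshold, and in MEFB H4K20me3 with H3Ac turned to 0.0077 (p = 0.86, permutation by shifts) and H3Ac with H3K9me3 weakened to -0.18. With input brightness regressed out these pairs stood at -0.14 and -0.18. The H3K4me3 profile of MEFB correlated at 0.71 with H4K20me3, 0.63 with H3K9me3, 0.40 with H3K9Ac and 0.31 with H4K20me1, and these became -0.23, -0.24, -0.59 and -0.41 with the dyes as labelled. The H3K27me3 profile of MEFF correlated at 0.07 with H4K20me3, 0.15 with H3K9me3, 0.13 with H3Ac, -0.11 with H4Ac and -0.08 with H3K4me2, and these became 0.58, 0.40, -0.21, -0.32 and 0.16. By the labels 11 MEFB pairs correlated above 0 and 13 below 0, and the MEFF counts were again 28 and 4.

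**Figure D4:**
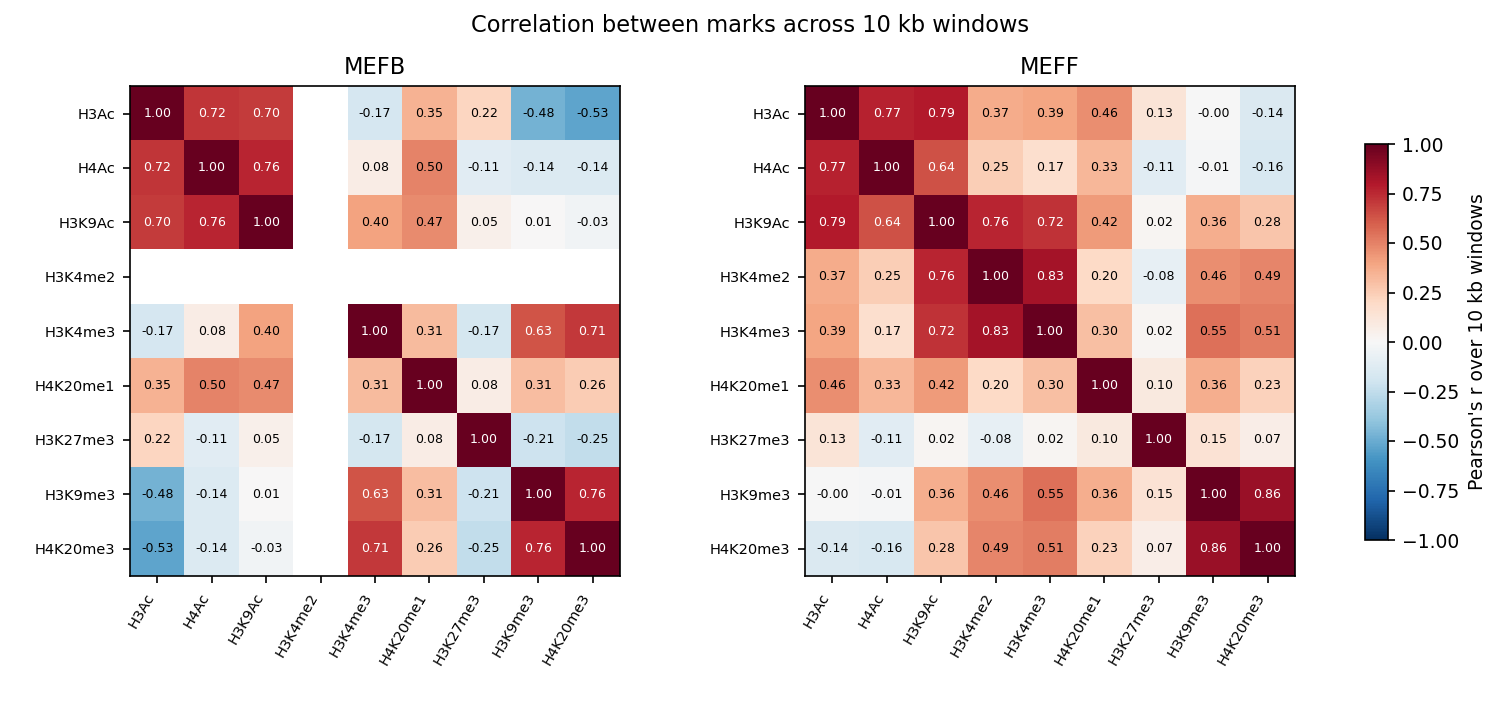
Pearson's r between the mean profiles of each pair of marks over 10 kb windows of chromosome 17, for MEFB (left) and MEFF (right), with the colour scale from -1 to 1 and H3K4me2 blank in MEFB. The acetylation marks form one block, and H4K20me3 and H3K9me3 correlate at 0.76 in MEFB and 0.86 in MEFF.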

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

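The tests on the extraction days, on the conflicting MEFF array and on the placement of the H3K27me3 windows, and the settings with labelled dyes and equal spread, were chosen only after the result was seen.

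The line differences of H3K27me3 and H4Ac had opposite signs and differed from each other in 131 windows, by limma's interaction of line and mark at an adjusted p of 0.05. In 1 of these windows both marks were called, and in 0 windows of the other pairs below, so the interaction shows unequal differences and not that each mark changed. At 78.45 Mb the differences were -1.47 for H3K27me3 and +0.51 for H4Ac, which was not called (limma adjusted p of the interaction = 3.85e-05), and at 82.14 Mb +0.64 for H3K27me3, which was not called, and -0.85 for H4Ac (limma adjusted p = 0.00813). H3K27me3 differed with opposite sign from H3Ac in 13 windows and from H3K9Ac in 13, led by 84.25 Mb with H3K27me3 at -0.92 and H3K9Ac at +1.39 (limma adjusted p = 0.0112). It did so from H3K9me3 in 3 windows and from H3K4me3 in 1, at 30.03 Mb (+0.21 and -0.64, limma adjusted p = 0.0448). H3Ac and H3K9me3, neither with a called window of its own at 10 kb, differed with opposite sign in 6 windows, led by 48.22 Mb (+0.77 and -0.53, limma adjusted p = 0.0266), and H4Ac and H3K9me3 in 1, at 57.54 Mb (-0.58 and +0.33, limma adjusted p = 0.0225). Limma gave 0 interaction windows for each of these pairs with the dyes as labelled. Windows of opposite sign at an unadjusted p under 0.05 then numbered 807 for H3K27me3 with H4Ac, 138 with H3Ac, 438 with H3K9Ac, 863 with H3K9me3 and 884 with H3K4me3, and for H3K9me3 they numbered 327 with H3Ac and 364 with H4Ac. By the labels H3K27me3 turned to 0.09 at 78.45 Mb and 0.26 at 84.25 Mb, and at 30.03 Mb it turned to -0.02 with H3K4me3 at -0.34, so these 3 windows no longer had marks of opposite sign. No array of H3Ac, H4Ac or H3K9me3 is turned by the labels, and their differences hardly moved. They were +0.77 for H3Ac and -0.54 for H3K9me3 at 48.22 Mb, and -0.58 for H4Ac and +0.33 for H3K9me3 at 57.54 Mb. The windows of this paragraph were chosen after their values were seen.

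H3K27me3 was higher in MEFF in 104 windows and higher in MEFB in 21. A narrower range of the single MEFB array leaves the calls in place in part: with equal spread 74 of the 104 windows, or 71.2%, kept their call, while the excess itself turned to 123 higher in MEFB and 84 in MEFF, so the range may explain the excess but not most of the windows. The MEFF array with conflicting dyes is not needed for the excess, since without it 72 windows were called higher in MEFF and 24 in MEFB, with 1 array per line whose spread was taken from the other groups. But that fit sets MEFB in Cy5 against MEFF replicate 1 in Cy3, so within this mark it cannot tell dye from line. Its dye correction came from the other marks. Leaving the array out replaced a test planned earlier, on the other MEFF array in windows called with its help, which could hardly have come out otherwise. Without the other MEFF array, replicate 1, both arrays left carried Cy5 in the deposited direction. The median difference was then -0.18 in the 4.6 Mb stretch starting at 9.82 Mb and +0.06 elsewhere. In the main fit these medians were -0.19 and +0.10. The dye was equal in that comparison, but it rests on 1 array per line and on the deposited direction. With the dyes as labelled limma called 0 windows (835 at an unadjusted p under 0.05). The days of extraction cannot be the source, since their number was 1. Random placement in 100 kb blocks gave at most 30 windows in the fullest stretch against 56. Blocks shorter than the largest cluster break it up, so chance placement of whole clusters stays open. By its labels the conflicting array correlated at -0.80 and -0.88 with the other arrays of its mark, which argues against the labelled direction. What stays open is a dye effect on this mark, a difference between single preparations, as MEFB has 1 array, and a biological difference between the lines. One such difference is the parental copy that each keeps. It was not tested, because the labels place the segment in mm9 and the build of the array positions is not given.

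H3K4me3, H3K9me3, H4K20me3 and H4K20me1 had profiles that resembled each other, with a median correlation of 0.438 over 12 pairs, or 0.306 with the dyes as labelled, by which 3 pairs with MEFB H3K4me3 turned from 0.71, 0.63 and 0.31 to -0.23, -0.24 and -0.41. A trend with the input brightness of the windows accounts for part of it at most: with that brightness regressed out the median was 0.356. Background at single probes is not removed by this, so its share stays open. A dye effect changed it little, to 0.409 with dye-corrected means, and loess within arrays raised it to 0.632. Input brightness correlated with H4K20me3 at -0.85 in MEFB and -0.81 in MEFF, with H3K9me3 at -0.67 and -0.56 and with H3K4me3 at -0.72 and -0.37. With H4K20me1 it correlated at -0.21 and 0.01. Low signal over background could thus still shape these profiles in other ways. The median does not show that H4K20me1 also tracked the acetylation marks. In MEFB it correlated at 0.50 with H4Ac, 0.47 with H3K9Ac and 0.35 with H3Ac. Its values with H4K20me3, H3K9me3 and H3K4me3 were 0.26, 0.31 and 0.31. In MEFF the same values were 0.33, 0.42 and 0.46, against 0.23, 0.36 and 0.30. No biological explanation was tested.

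Control probes that the comparisons did not use carried signal. In the deposited direction the 5000 chr2L control probes of 5 arrays had a median log2 ratio of 0.53 against chromosome 17 (range 0.38 to 0.67), and 4000 random-mutation probes had 0.53. Both medians are the values of MEFB H3K4me3 replicate 1, which its labels would turn negative. The chr2L probes reached 85.1% to 92.3% of the chromosome 17 intensity in the ChIP channel and 48.8% to 60.7% in the input channel. In the deposited direction these probes passed 0.5, the level used for enrichment, on 3 of the 5 arrays, so an enriched share is relative to the chromosome's median and does not measure signal over untargeted probes. The other arrays were not compared with control probes. The 2 MEFB H3K4me2 arrays without positions correlated at 0.629 over their probes.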

How the results depend on the processing

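The settings with labelled dyes, without the conflicting arrays, with equal spread, extraction day or input brightness were chosen only after the data had been seen. Of 29 named windows 0 kept their call under all 15 settings. The labelled dyes alone fix this, since with them limma called 0 windows for H3K27me3, H4Ac, H3K9Ac and H3K4me3. In the other settings the 10 named H3K27me3 windows kept their call, except 1 without the conflicting arrays. The 10 of H4Ac did so except 7 with the day as a term. The 8 of H3K9Ac and the 1 of H3K4me3 lost theirs with the day and with each mark fitted alone, and some were lost elsewhere. Over these settings and leave-one-out, 403 values were the same, 125 weaker and 3 reversed. With the dyes as labelled H3K27me3 turned to 0.093 at 78.45 Mb, 0.0449 at 13.30 Mb and 0.071 at 84.02 Mb. Over 20 mark pairs and their settings, 234 correlations kept their direction and side of the threshold, though in MEFB H4K20me3 with H3Ac fell from -0.53 to -0.14 and H3Ac with H3K9me3 from -0.48 to -0.18 (brightness); 16 lost the threshold and 19 reversed. With loess H4K20me3 turned to 0.0077 with H3Ac in MEFB and 0.0442 with H4Ac in MEFF, and with brightness to 0.23 with H4Ac and 0.17 with H3Ac in MEFF. With labelled dyes MEFB H3K4me3 turned to -0.23 (H4K20me3), -0.24 (H3K9me3), -0.59 (H3K9Ac) and -0.41 (H4K20me1), and MEFF H3K27me3 to -0.21 (H3Ac) and 0.16 (H3K4me2). MEFF H3K27me3 turned to 0.0515 with H3K4me2 (Spearman), to -0.0925 with H4K20me3 and 0.057 with H4Ac (100 kb), to -0.23 with H4K20me3, -0.0113 with H3K9me3 and 0.42 with H4Ac (1 Mb), and with H4K20me3 ranged from -0.0927 to 0.20 in leave-one-out (reversed without MEFF H3K27me3 replicate 1). At 1 Mb MEFB H3K4me3 turned to -0.15 with H3K9Ac and -0.019 with H4K20me1. The cause was not tested. Signal over background was not compared between marks, as control probes were on 5 arrays of 3 marks only. There they stood at 0.38 to 0.67 in the deposited direction. The comparisons inside and outside the segment and over genes were not run, and H4K20me3 alone has no residual degrees of freedom.

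Called windows moved as follows, and the cause was not tested. Labelled dyes turn arrays of H3K27me3 and H3K4me3 only, so for H4Ac and H3K9Ac they changed the shared spread and not the differences. H3K27me3 (125): design term 222, normexp 476, quantile 327, 50 kb 35, without dim probes 203, alone 192, labelled dyes 0, without the conflicting arrays 82, equal spread 207, brightness 663, leave-one-out 14 to 96. H4Ac (41): design 139, normexp 131, loess 271, quantile 487, 50 kb 1, without dim probes 123, alone 403, labelled 0, equal spread 101, day 10, brightness 586, leave-one-out 0 to 6. H3K9Ac (8): loess 33, quantile 25, 2 kb 45, 50 kb 0, without dim probes 14, alone 0, labelled 0, equal spread 27, day 0, brightness 162, leave-one-out 2 to 513. H3K4me3 (1): no dye term 2, 2 kb 4, equal spread 7, and 0 with normexp, loess, quantile, 50 kb, alone, labelled dyes, without the conflicting arrays, day or brightness, leave-one-out 0 to 1. H3Ac (0): design 42, number-sharing H3K9me3 arrays as 2 replicates 1, quantile 84, 50 kb 13, without dim probes 9, equal spread 42, brightness 75, leave-one-out 0. H4K20me1 (0): quantile 2, 2 kb 1, alone 261, equal spread 2, brightness 11, leave-one-out 0 to 1. H3K9me3 (0): quantile 1, 2 kb 3, alone 9, equal spread 1, leave-one-out 0. The ranges below span settings with different numbers of windows, 8241 of 10 kb, 34458 of 2 kb and 1774 of 50 kb. Both ends for H4K20me3 came from windows of 50 and 2 kb, and the upper end for H3Ac from 2 kb. Where limma called 0, windows at an unadjusted p under 0.05 numbered 835 for H3K27me3, 455 to 1171 for H4Ac, 190 to 808 for H3K9Ac, 45 to 2049 for H3K4me3, 95 to 2235 for H3Ac, 31 to 395 for H4K20me1, 72 to 1303 for H3K9me3 and 2 to 642 for H4K20me3.

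Enriched shares in percent moved with normexp to 9.51 (H3K27me3), 6.99 (H4K20me3), 8.49 (H4Ac), 10.01 (H3K9Ac), 2.97 (H3K9me3), 15.1 (H3K4me2) and 3.86 (H3K4me3), with loess to 1.09 (H3K27me3), 1.33 (H3Ac) and 0.692 (H4Ac), and with labelled dyes to 0 (H3K27me3). A threshold of 1 gave 0.583 (H3K27me3), 0 (H4K20me3), 0.740 (H3Ac), 0.0243 (H4Ac) and 1.89 (H3K4me2). Windows of 2 kb gave 1.34 (H4K20me3), 5.44 (H4K20me1), 6.10 (H4Ac), 1.52 (H3K9me3) and 7.70 (H3K4me2), and 50 kb gave 0 (H4K20me3), 1.97 (H4Ac) and 2.37 (H3K4me2). Leave-one-out ranges were 4.85 to 5.24 (H3K27me3), 0.655 to 3.01 (H4K20me1), 4.99 to 7.86 (H3Ac), 3.25 to 4.39 (H4Ac), 0.0121 to 0.243 (H3K9me3), 2.45 to 4.89 (H3K9Ac), 5.99 to 6.83 (H3K4me2) and 0.425 to 2.09 (H3K4me3). Mark pairs below 0 moved in MEFB from 9 to 5 (normexp) and 1 (loess), and in MEFF from 4 to 2 (loess, brightness and Spearman); leave-one-out gave 12 to 18 above and 7 to 11 below in MEFB, 26 to 28 and 3 to 4 in MEFF. The cause was not tested. The gap between same and different marks stayed within 0.377 to 0.576.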

Other observations

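The test on the distance of the facing sites and the choice of the regions named in this part came only after the result was seen.

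Other marks were examined at the called windows, with no test of the shared direction. The shares over all windows are not given here, so a difference along the whole chromosome is not excluded. Neighbouring windows are not independent. At the 34 windows with more H4Ac in MEFF, H3K9Ac was lower in MEFB in 34 of 34 (median -0.31, 2 called), H3K4me3 in 29 (median -0.18, 1 called) and H3Ac in 28 (median -0.10), while H3K27me3 was lower in MEFB in 4 (median +0.20) and H4K20me1 in 9 (median +0.07). By the labels H3K4me3 was lower in 12 (median +0.025) and H3K27me3 in 12 (median +0.13). At the 7 windows with more H4Ac in MEFB, H3Ac and H3K9Ac were higher there in 7 of 7, by medians of +0.58 and +0.51. At the 104 windows with more H3K27me3 in MEFF, H4K20me1 was lower in MEFB in 97 (median -0.14), H3K4me3 in 98 (median -0.11) and H3K9me3 in 74 (median -0.08), with none of these called, while among the acetylation marks H3K9Ac was lower in 79 (median -0.13), H4Ac in 35 (median +0.11) and H3Ac in 43 (median +0.03). By the labels H3K4me3 was lower in 48 (median +0.0245), and H3K27me3 itself in 43 (median +0.05), so the choice of these windows rests on the deposited direction.

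H3Ac was higher in MEFB along a stretch from 47.65 to 48.40 Mb, drawn around the 13 windows of 50 kb that limma called for H3Ac (adjusted p 0.0113 to 0.046). Its 10 kb windows were higher in MEFB in 75 of 75, with medians of 0.17 in MEFB and -0.41 in MEFF (+0.58, 0 called by limma at 10 kb and 462 along the chromosome at an unadjusted p under 0.05). H4Ac was higher in 70 of the windows (+0.36, 4 called), H3K27me3 in 75 (+0.26, 7 called) and H3K9Ac in 62 (+0.15), while H3K4me3 was higher in 5 (-0.14) and H3K9me3 in 2 (-0.17). By the labels H3K27me3 was higher in 62 (+0.14), H3K4me3 in 59 (+0.18) and H3K9me3 in 2 (-0.19), and limma called 0 of these windows for H3Ac, H4Ac or H3K27me3 (70, 35 and 9 at an unadjusted p under 0.05). H3Ac and H4Ac stayed at +0.58 in 75 windows and +0.36 in 70, since none of their arrays is turned. Single H3Ac arrays had 0.23 and 0.10 in MEFB and -0.55 and -0.27 in MEFF. A lower input in MEFB does not account for it, because the input differed by -0.038 (spread 0.029). The pair extracted on 1 day differed by 0.38, more than 0.5 times the full difference but by less than its spread of 0.22. The bound as first written would have excluded the days, and the spread was added to it after the value was seen, so a difference between days stays possible, and so does a difference between the lines, which was not tested in other material.

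Near 12 Mb H3K4me3 and H3K9Ac were higher in MEFF at 12.150 Mb. At 12.176 Mb H3Ac and H3K9Ac had higher means in MEFB, but no mark passed the threshold there (limma adjusted p = 0.199 and 0.0622), so an opposite site is not established. In the labels' account the lines keep different parental copies of a segment with the Igf2r cluster. If the maternal chromosome is written first, an assumption that the labels do not state, MEFB keeps the maternal and MEFF the paternal copy. A candidate explanation is that the 2 places are the promoters of Airn and Igf2r, whose activity depends on the parental copy. The sites lie 26 kb apart and the annotated starts of these genes 28.4 kb, a difference of 2.35 kb that falls between the 2 kb and 4 kb bounds set for the test, so the distance left this open. No coordinate was converted between builds, and the sites' genes are not known from these files.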
